A study of Homo sapiens with 13 samples.

How the data were processed

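Polyadenylated RNA was sequenced from 13 human samples. 3 came from K562, a human erythroleukemia cell line, and 10 from primary cord blood CD34+ cells, which are blood stem and progenitor cells here grown towards red cells. RNA was extracted with a ZYMO column kit, enriched for polyadenylated molecules and made into directional libraries with NEBNext reagents. The labels name cutadapt, TopHat2 2.0, Bowtie2, featureCounts and DESeq2 as the authors' tools and state a version only for TopHat2. They list the genome builds hg38 and hg19 with no role for either. The annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The deposited tables hold raw counts per gene, whole numbers with no normalization, for 60675 Ensembl gene IDs. Reads from near-identical genes, such as HBA1 and HBA2 or HBG1 and HBG2, can be lost or exchanged between the copies, so these pairs are best read together.

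Columns were assigned to samples through their names. The K562 table has a pair of columns for each of the 2 knockdown clones. Each pair was summed as 1 clone, since its names share the clone number and its columns differed by a mean chi-square per gene of 4.89 and 2.05, while columns of different clones differed by 50.1 to 55.4. Whether a pair is 2 sequencing runs or 2 cultures of a clone is not given in the sources used here, and the chi-square does not decide it, since cultures of the 2 titled CD34+ arms differed by 3.24 to 4.99. 1 further K562 column, named WT2 beside the control column WT1, reads as a second control by its name. It matches no sample label and was not used, so that the K562 control is 1 library. In the CD34+ table the third arm carries the column name OE, which no label uses, and it was assigned to the samples titled Rescue by elimination within each day. The titles and the genotype fields of the CD34+ samples disagree. Samples titled KD have the genotype of ncRNA-a3 siRNA plus Tal1, and samples titled Rescue have that of the siRNA alone. Groups follow the titles throughout, and the mean of both titled arms against scramble siRNA does not depend on which reading is right.

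Gene names were matched for 56558 IDs, and coordinates were taken from GENCODE 29 on GRCh38, which held 57055 of the IDs. XIST, TSIX and genes of the Y chromosome (517 IDs) were left out. The targeted RNA, ncRNA-a3, was identified as CYP4A22-AS1 from general knowledge of its names, since the labels do not give an ID for it. 24 gene lists were written from general knowledge, and 443 of their 444 members matched an ID. They cover the TAL1 locus, the TAL1 complex, erythroid transcription factors, globins, heme synthesis, red cell membrane proteins, late erythroid genes, stem and progenitor genes, megakaryocyte, granulocyte, monocyte, mast cell with eosinophil and basophil, lymphoid and dendritic cell genes. The others are DNA replication, mitosis, interferon, p53 target, stress response (unfolded protein and amino acid response), cholesterol synthesis, glycolysis and hypoxia, immediate early, ribosomal protein and mitochondrially encoded genes. A few genes stand on more than 1 list. The groups, comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where a fit, setting or test is said to have been added.

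Counts were scaled with TMM factors and tested with edgeR 4.0.16 (filterByExpr, robust quasi-likelihood F-test, two-sided) in R 4.3.3. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. K562 knockdown clones were compared with the empty vector in a fit of 3 libraries with 1 residual degree of freedom. The 9 CD34+ libraries of days 3, 7 and 14 were fitted with day and arm as additive terms and 4 residual degrees of freedom, which finds only differences shared by the days or by the arms. A further fit was added after it was seen that the additive fit called no gene for the siRNA and that its effects differed by day. It has an siRNA effect for each day, takes the libraries titled KD and Rescue of a day as 2 siRNA libraries and has 3 residual degrees of freedom. In that fit the lone scramble library of each day is assumed to vary as the siRNA libraries do, and so is the lone control in K562. All p values therefore measure only the spread between these samples. In the fit by day this is the spread between the 2 titled libraries of a day, 1 of which also received Tal1 by the labels. The fitted coefficient of variation between libraries was 0.0486 in that fit and 0.216 in the additive fit. The spread of the additive fit also holds effects that differ by day. The day 0 library belongs to no arm and was compared with the day 3 scramble library without a test, as log2 ratios with a pseudocount of 2 CPM. CPM are counts per library total times its TMM factor. For CD34+ cells the factors behind the CPM were set over 10 libraries, day 0 included, and those of the fits over the 9 tested ones. On day 14 log2 ratios of siRNA to scramble taken from the CPM are therefore lower than fitted ones by 0.095 for the library titled KD, 0.21 for the one titled Rescue and 0.15 on average, and by 0.025 on average on day 7. List medians were placed among those of 10000 random lists matched for expression.

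Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01), adjusted over the lists of a comparison, then with an estimated correlation and with fry. With an estimated correlation no list passed in any comparison, and the adjusted p values are given beside those with the preset one. Genes are named by a rule. It takes the detected genes of the TAL1 locus and a core panel of 23 genes. It adds, per comparison, the 10 largest rises and falls past the threshold with a mean of at least 5 CPM and the same direction in every clone, day or arm. From each list it takes up to 4 members with the smallest p past the threshold, or up to 2 abundant members if none passed. WIPI1, EGR1 in K562, EPX between days 7 and 3, and SLC25A37, CDKN1A, BNIP3L and HMGCS1 between days 14 and 3 lie outside this rule and were chosen after values were seen. The text gives part of the genes that the rule takes, and others, including some of the core panel, are not reported here. Day 0 genes named by value were also chosen after values were seen.

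Errors of log2 fold changes, called standard errors (SE), are the absolute change divided by the square root of its F statistic. They approximate a standard error and should not be read as one where a group has a count of 0. Ratios of the targeted RNA and TAL1 in single libraries carry exact Clopper-Pearson intervals at 95%, and shares of counts carry Wilson intervals at 95%. Intervals and the floor of 3 counts, which is the upper limit that a count of 0 allows, cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The floor, scaled as the CPM, ranged from 0.0725 CPM in the day 14 scramble library to 0.415 CPM in the day 14 library titled Rescue.

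The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold per comparison. These were taken from genes with a mean of at least 5 CPM, and the heme synthesis list was raised 2-fold as well. In the fit by day the simulated scramble library varied as the siRNA libraries do. Calls in error therefore do not cover a scramble culture that stands apart. For K562, edgeR recovered 15% of genes changed 2-fold and 76% of those changed 4-fold. For the siRNA in the additive fit it recovered 70% and 100%, for day 14 against day 3 it recovered 52% and 96%, and for the siRNA on day 7 in the fit by day it recovered 92% and 99%. Between 13 and 32 unchanged genes were called in error with edgeR and between 21 and 63 with DESeq2 (48 for the siRNA in the additive fit), and no unchanged list passed. Simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. Alternatives were RLE, upper quartile and total count scaling, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, no block, a dispersion from the CD34+ fit for K562, a pseudocount of 0.5 CPM, and leaving out each clone, day or arm. The CD34+ dispersion was set as a common value for all genes and tested with a likelihood ratio test in place of the F-test. Scaling by totals, every alternative of the fit by day, leaving out the day 14 library titled KD, and thinning the day 14 scramble library to 19.67% of its counts were chosen after seeing the data. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.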

Results

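RNA sequencing covered 13 samples. The K562 line was measured as 1 culture with an empty pLKO.1 vector and 2 clones with knockdown of the noncoding RNA ncRNA-a3 (CYP4A22-AS1). Cord blood CD34+ cells were measured untreated on day 0 in 1 library, and on days 3, 7 and 14 of culture in 3 arms of 1 library per day. The arms are scramble siRNA, the library titled KD and the library titled Rescue. Both titled arms received the ncRNA-a3 siRNA, and the labels disagree on which of them also received Tal1. The K562 control had 14213969 counts and the clones had 34248799 and 33487533. The day 0 library had 24323384 counts. On day 3 the scramble, titled KD and titled Rescue libraries had 25646978, 23735913 and 32217577 counts, on day 7 they had 22874177, 34999464 and 27679617, and on day 14 they had 56769373, 18634571 and 11166897. There are no replicate libraries within an arm and day.

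The targeted RNA was scarce in every sample. CYP4A22-AS1 (ENSG00000225506) is a long noncoding RNA on the minus strand of chromosome 1, from 47096653 to 47179271 on GRCh38, and its span overlaps CYP4Z1 and CYP4A22. In K562 it had 8 counts (0.556 CPM) in the control and 4 and 5 counts in clones 1 and 2. Relative to the control this was 0.203 (95% interval 0.0447 to 0.757) in clone 1 and 0.282 (0.0726 to 0.978) in clone 2, with a fitted log2 change of −2.01 ± 0.92 (SE, n = 2 clones against 1 control, adjusted p = 0.635). In CD34+ cells it had 28 counts (0.918 CPM) on day 0, and 0.373 CPM on day 3, 1.29 CPM on day 7 and 2.39 CPM on day 14 with scramble siRNA. On day 3 the ratio to scramble was 1.25 (0.535 to 2.95) in the library titled KD and 1.41 (0.662 to 3.14) in the one titled Rescue. On day 7 the ratios were 0.732 (0.443 to 1.21) and 0.581 (0.326 to 1.02), so that no reduction was detectable at this depth. On day 14 they were 1.62 (1.11 to 2.33) and 2.25 (1.51 to 3.30), above scramble in both siRNA libraries. The fitted siRNA effect of day 14 was 1.07 ± 0.36 (adjusted p = 0.0284), a call that was lost with DESeq2 (adjusted p = 0.0827), with totals as the scaling (0.129), with no filter (0.119), with the day 14 scramble library thinned (0.130) and without the day 14 library titled Rescue (log2 0.79, adjusted p = 0.118). It was also lost without the day 3 library titled KD (0.0613) or titled Rescue (0.0614).

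TAL1, a transcription factor needed for blood and red cell formation, was lower in the siRNA libraries than in the lone scramble library on day 7 and higher on day 14. TAL1 (ENSG00000162367) lies on the same strand of chromosome 1, from 47216290 to 47232220. In K562 it measured 150.7 CPM in the control, 55.1 CPM in clone 1 and 113.8 CPM in clone 2. These are ratios of 0.365 (0.344 to 0.389) and 0.756 (0.716 to 0.797), which differ more between clones than counting allows, and the fitted change was −0.84 ± 0.48 (adjusted p = 0.678). In CD34+ cells TAL1 measured 70.8 CPM on day 0, and 63.7, 416 and 1424 CPM with scramble siRNA on days 3, 7 and 14. On day 7 it fell by 0.24 ± 0.06 on the log2 scale with siRNA (n = 2 libraries against 1, adjusted p = 0.00953), to 340 CPM in the library titled KD and 351 CPM in the one titled Rescue. Without the day 7 library titled KD the change was −0.20 (adjusted p = 0.117). On day 14 it rose by 0.57 ± 0.07 (adjusted p = 2.58e-06), with 1916 and 1902 CPM on the scaling that includes day 0. The rise was 0.21 with totals as the scaling (adjusted p = 0.0101) and 0.36 with no filter (8.74e-08). On day 3 the value was −0.27 ± 0.07 (adjusted p = 0.125), which passed the threshold with no filter (0.0110) and without the day 14 library titled KD (0.00467) or titled Rescue (0.00459). The effects of days 7 and 14 differed by 0.81 ± 0.09 (adjusted p = 2.66e-06). These errors and p values rest on the spread between the 2 siRNA libraries of a day. They do not cover variation between scramble cultures, of which each day has 1.

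**Figure D1:**
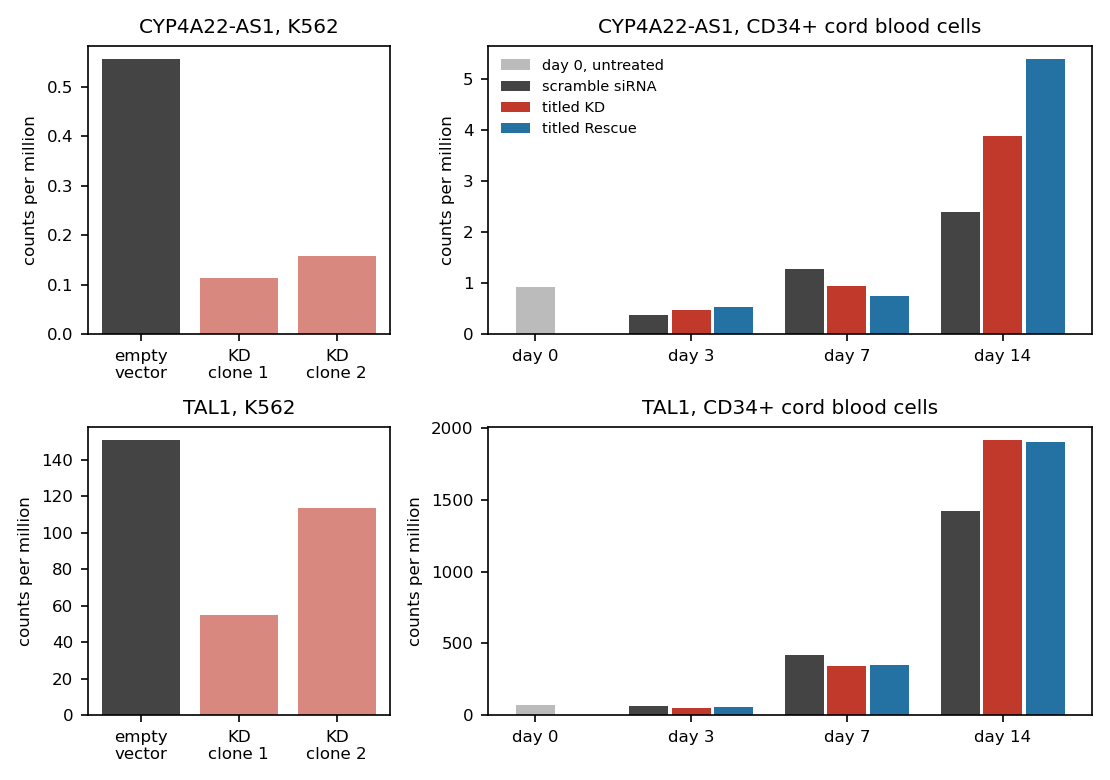
Normalised counts (CPM, linear axes from 0) of CYP4A22-AS1 and TAL1, with 1 bar per library and no error bars, since no library has a replicate. With siRNA, TAL1 lies below scramble on day 7 (340 and 351 against 416 CPM) and above it on day 14 (1916 and 1902 against 1424 CPM).

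Genes beside TAL1 behaved unequally. PDZK1IP1, the neighbour between CYP4A22-AS1 and TAL1 (47183593 to 47191044), measured 1.79 CPM on day 7 with scramble siRNA, 0.548 CPM in the library titled KD and 0.747 CPM in the one titled Rescue. On day 14 it measured 30.4, 59.0 and 56.9 CPM, with a fitted rise of 1.08 ± 0.14 (adjusted p = 7.70e-06), and the difference between days was 2.54 ± 0.35 (adjusted p = 2.34e-05). STIL (47250139 to 47314147), a centriole protein, measured 247.3 CPM with scramble siRNA on day 14, 161.2 CPM in the library titled KD and 153.7 CPM in the one titled Rescue. Of the 10 tested genes of the locus list, 1 rose and 4 fell on day 7, and 5 rose and 2 fell on day 14. With totals as the scaling, 2 rose and 3 fell on day 14. The list test gave an adjusted p of 0.0912 on day 7 (0.537 with an estimated correlation) and 0.101 on day 14 (0.519 with an estimated correlation).

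The K562 comparison sets 2 clones with knockdown of ncRNA-a3 against 1 control culture of an erythroid line. An effect of the knockdown cannot be told apart from other differences between clones. The control differed from the columns of clone 1 by a mean chi-square per gene of 67.9 and 70.9, and from those of clone 2 by 49.5 and 50.8. Columns of the 2 clones differed from each other by 50.1 to 55.4. Several red cell genes were lower in both clones than in the control. SLC4A1, the anion exchanger of the membrane, had a log2 difference of −2.71 ± 0.46 (SE, n = 2 clones against 1 control). HBA2 differed by −1.57 ± 0.24, HBA1 by −1.14 ± 0.25, HBE1 by −1.35 ± 0.30 and SLC25A37, the mitochondrial iron importer, by −1.61 ± 0.26. ITGA2B, a platelet integrin, was higher in both clones, at 52.1 and 67.7 CPM against 12.2 CPM (2.30 ± 0.31). EGR1, an immediate early gene, measured 330 CPM in the control and 21.2 and 45.1 CPM in the clones (−3.32 ± 0.49). CD74, part of antigen presentation, was higher by 5.12 ± 0.78 and LYZ, a macrophage and granulocyte enzyme, by 1.47 ± 0.26. Erythroid transcription factors differed less: NFE2 by −0.84 ± 0.22, GATA1 by 0.48 ± 0.32, LMO2 by −0.27, KLF1 by −0.24, GFI1B by −0.17, GATA2 by 0.19 and MYB by 0.17. KIT differed by −1.53 ± 1.06, TFRC by −0.65 ± 0.38, HBG2 by −0.45, ALAS2 by −0.44 and HBB, at 0.417 CPM in the control, by −0.36 ± 0.87.

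None of these K562 differences passed over all genes with edgeR, where 0 of 19369 genes were called, 1539 had an unadjusted p under 0.05, and the smallest adjusted p was 0.610. DESeq2 called 185 genes, 109 higher and 76 lower, among them EGR1 (adjusted p = 9.44e-09), ITGA2B (2.26e-05), SLC4A1 (0.00354), SLC25A37 (0.00582), CD74 (0.00604), HBA2 (0.00811) and LYZ (0.0414). Of the red cell membrane list, 0 of 21 tested genes passed over all genes and 7 were lower when adjusted over the list alone (median −0.93, list test adjusted p = 9.57e-05). Of the globins, 0 of 10 passed and 4 were lower when adjusted over the list alone (median −0.79, adjusted p = 0.00295). Immediate early genes had 3 of 16 lower when adjusted over the list alone (median −0.47, adjusted p = 0.00295). Mitosis genes lay higher as a list (median 0.67, adjusted p = 0.000262), with TOP2A at 0.87 ± 0.27 and TPX2 at 0.67 ± 0.31. Late erythroid genes (adjusted p = 0.0254), heme synthesis (0.0404) and mitochondrially encoded genes (0.0160, median −0.51) lay lower. These 7 of 23 lists were lost with an estimated correlation, where each had an adjusted p = 0.874, and fry called 0 lists. The counts rest on the fitted spread, the test and the filter. With the common dispersion of the CD34+ fit 1566 genes passed, but in a likelihood ratio test, so test and dispersion changed together. With no filter 745 genes passed. Globin genes held 0.329% of counts in the control (Wilson interval 0.326 to 0.332) and 0.149% and 0.139% in clones 1 and 2, and mitochondrial genes held 6.58%, 4.87% and 4.78%.

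Culture from day 0 to day 3 was compared without a test because each has 1 library, and mitosis and myeloid genes were higher on day 3 and progenitor genes lower. Mast cell, eosinophil and basophil genes were higher on day 3 for 16 of 16 members (median log2 difference 3.37), with EPX, the eosinophil peroxidase, going from 6.03 to 1374 CPM. Mitosis genes were higher for 22 of 22 members (median 3.45), with TOP2A at 9.77 and 512 CPM. Monocyte genes were higher for 20 of 20 (median 2.15), and MPO, the neutrophil peroxidase, measured 846 CPM on day 0 and 7689 CPM on day 3. Stem and progenitor genes were lower for 22 of 24 (median −1.75), with CD34 at 796.5 and 323.1 CPM and HLF at 132.8 and 5.59 CPM. Immediate early genes had a median of −1.94, with FOS at 130.8 and 11.6 CPM, and ribosomal protein genes were lower for 32 of 32 (median −0.91). Each of these medians stood at a percentile of 0 or 100 among 10000 random lists, and 13 lists lay outside their central 95% (14 with a pseudocount of 0.5 CPM).

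From day 3 to day 14 most genes of the erythroid lists rose. All 11 globin genes, all 12 heme synthesis genes and all 22 red cell membrane genes rose between these days, as did 23 of 25 late erythroid genes and 14 of 16 erythroid transcription factors (1 fell). HBB measured 2.0, 2.2 and 3.4 CPM on day 3 in the scramble, titled KD and titled Rescue libraries and 26820, 66240 and 57480 CPM on day 14. KLF1, the erythroid Krüppel-like factor, rose by 9.33 ± 0.22 (SE, n = 3 libraries per day), GATA1 by 5.21 ± 0.23, TAL1 by 5.07 ± 0.25 and SLC25A37 by 8.58 ± 0.37. MYB, the erythroid transcription factor that fell, changed by −3.21 ± 0.26, and KIT fell by 2.57 ± 0.21, GATA2 by 2.82 ± 0.30 and MPO by 4.99 ± 0.31. TAL1 rose by 2.70 ± 0.22 from day 3 to day 7 and by 2.37 ± 0.22 from day 7 to day 14, and CYP4A22-AS1 rose by 3.15 ± 0.43 from day 3 to day 14 (adjusted p = 0.00027).

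Genes of other lineages mostly declined over the same days. From day 3 to day 14, 15 of 16 mast cell, eosinophil and basophil genes fell, as did 15 of 20 monocyte genes (1 rose), 11 of 12 dendritic genes and 10 of 14 lymphoid genes (3 rose). EPX rose by 0.93 ± 0.26 by day 7 (adjusted p = 0.0190, lost without the titled KD arm at 0.109 and without the titled Rescue arm at 0.186) and fell by 9.05 ± 0.37 from day 7 to day 14. Of 15 granulocyte genes 9 fell and 5 rose, so that the list median was −1.90 and its mean 0.09. Megakaryocyte genes rose in 15 of 21 cases and fell in 4. Stem and progenitor genes fell in 19 of 24 cases and rose in 1, and CD34 itself fell by 5.77 ± 1.49 (adjusted p = 0.00816), a call lost without the scramble arm (−3.81, adjusted p = 0.0768), without the titled Rescue arm (−4.69, 0.0640) and with no filter (0.0881). Of mitosis genes 21 of 22 rose, of p53 targets 16 of 20 rose and 1 fell, and of stress response genes 13 of 18 rose and 4 fell. CDKN1A, a p53 target, rose by 2.40 ± 0.15, and BNIP3L, which clears mitochondria in red cell precursors, rose by 4.64 ± 0.33. Mitochondrially encoded genes fell in 12 of 13 cases, and the mitochondrial share of counts was 7.74% on day 3 (Wilson interval 7.73 to 7.75) and 2.20% on day 14 (2.19 to 2.20) with scramble siRNA.

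The remaining lists went both ways between days 3 and 14. Immediate early genes rose in 10 of 16 cases and fell in 2, DNA replication genes rose in 8 of 22 and fell in 3, and interferon genes rose in 10 of 23 and fell in 13. Glycolysis and hypoxia genes rose in 9 of 21 and fell in 12, cholesterol synthesis genes rose in 3 of 18 and fell in 5, and ribosomal protein genes rose in 2 of 32 and fell in 4. HMGCS1, which makes the precursor of mevalonate, had a change of 0.76 ± 0.47 (adjusted p = 0.173). With edgeR, 4271 genes rose and 4378 fell from day 3 to day 7, 5267 rose and 6099 fell from day 7 to day 14, and 6534 rose and 7136 fell from day 3 to day 14, of 18943 tested. List tests passed for 18 of 24 lists between days 14 and 3, and none passed with an estimated correlation (adjusted p = 0.209 to 0.956). Scaling by totals moved the median of all genes by −1.03 for day 14 against day 3, by −0.84 for day 14 against day 7 and by −0.18 for day 7 against day 3. It kept 77.7%, 76.8% and 83.4% of the calls of these comparisons in the same direction, and 534, 265 and 0 passed in the opposite one. Under this scaling the 22 DNA replication genes turned to 2 higher and 15 lower, the 22 mitosis genes to 10 higher and 0 lower and the 32 ribosomal protein genes to 0 higher and 32 lower, while the globin, heme and red cell membrane counts stood. The count for day 7 against day 3 was 4765 without the titled KD arm and 3922 without the titled Rescue arm, and for day 14 against day 7 it was 6849 without the titled Rescue arm.

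**Figure D2:**
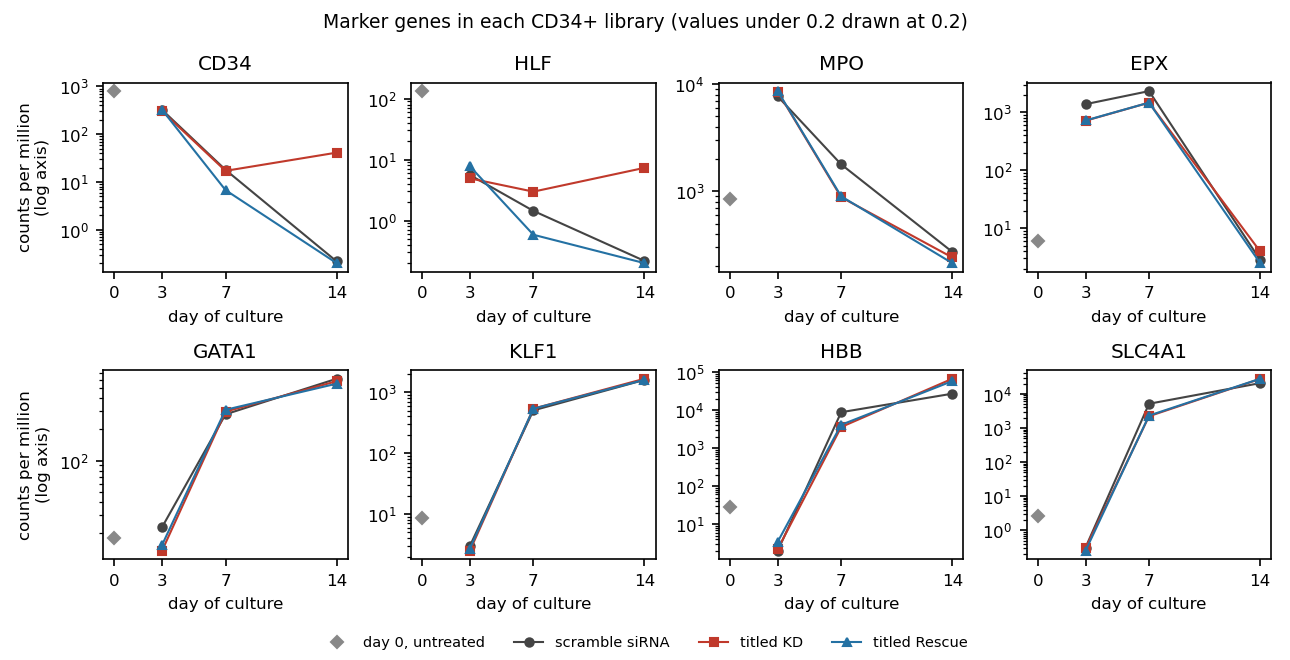
Normalised counts (CPM, log axes) of 8 marker genes against day of culture, with 1 point per library and a line per arm, values under 0.2 CPM being drawn at 0.2. HBB goes from between 2.0 and 3.4 CPM on day 3 to between 26820 and 66240 CPM on day 14, and CD34 ends at 41.1 CPM in the day 14 library titled KD against 0.2 and 0.1 CPM in the other day 14 libraries.

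The siRNA was first compared with scramble across all days, which asks for effects that days 3, 7 and 14 share. Mast cell, eosinophil and basophil genes lay lower as a list (median −0.60, list test adjusted p = 1.88e-10, adjusted p = 0.422 with an estimated correlation), with 0 of 16 past the threshold over all genes and 10 lower when adjusted over the list alone. Megakaryocyte genes lay lower too (median −0.49, adjusted p = 1.30e-12, and 0.422 with an estimated correlation), with 0 of 21 past the threshold and 8 lower when adjusted over the list alone. ITGA2B differed by −0.53 ± 0.10 (SE, n = 6 siRNA against 3 scramble libraries), EPX by −0.52 ± 0.23 and HBE1, the embryonic globin, by 1.72 ± 0.32. WIPI1, an autophagy protein, differed by −0.89 ± 0.09 (adjusted p = 0.210) and passed with DESeq2 (1.19e-10) and with no filter (0.000609). TAL1 differed by 0.00 ± 0.18 (adjusted p = 0.999).

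With edgeR 0 genes passed for the siRNA across days, 1033 had an unadjusted p under 0.05, and DESeq2 called 24 (10 higher, 14 lower). In simulated data DESeq2 called 48 unchanged genes, but those data also held changed genes. The 48 are therefore not the number expected without an effect, and how many of the 24 are errors was not tested. Granulocyte genes (median −0.46, adjusted p = 1.91e-06), glycolysis and hypoxia genes (0.000122), ribosomal protein genes (6.34e-05), mitosis genes (0.000449), cholesterol synthesis genes (0.0142), monocyte genes (0.0235) and red cell membrane genes (0.0495) lay lower, and mitochondrially encoded (1.48e-07, median 0.38) and immediate early genes (0.0121) lay higher. All 11 list calls were lost with an estimated correlation (adjusted p = 0.422 to 0.750). Mitochondrial genes held 7.18% and 6.71% of counts in the siRNA libraries of day 7 against 6.35% with scramble, and 2.90% and 2.86% against 2.20% on day 14. Scaling by totals moved the median of all genes by −0.13 in this comparison.

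Arm by arm, the library titled KD and the library titled Rescue differed little on days 3 and 7 and by more on day 14. Neither arm had a gene past the threshold against scramble with edgeR, where 699 genes of the titled KD arm and 665 of the titled Rescue arm had an unadjusted p under 0.05. DESeq2 called 33 genes (3 higher, 30 lower) for the titled KD arm and 40 (4 higher, 36 lower) for the titled Rescue arm. Both arms share the same 3 scramble libraries. Their log2 changes correlated at r = 0.521 across genes, which are not independent replicates, against 0.440 in simulated data with no effect, and the 3 controls cannot be split to remove this sharing. TAL1 differed from scramble by −0.04 ± 0.21 in the titled KD arm and by 0.05 ± 0.21 in the titled Rescue arm. The labels set the titled arms apart by Tal1. Between them TAL1 differed by 0.08 ± 0.21 (titled Rescue minus titled KD, n = 3 days). With edgeR 0 genes passed, 51 had an unadjusted p under 0.05 and DESeq2 called 50. The error of this contrast also holds the change of the siRNA effect between days, which both titled arms share. A fit of the 2 titled arms alone, without scramble, called 0 genes too. Stem and progenitor genes were the only list of 24 to pass, lower in the titled Rescue arm (median −0.81, adjusted p = 2.88e-07, adjusted p = 0.931 with an estimated correlation), with CD34 at −2.22 ± 1.38. Without the day 14 library titled KD their median was −0.07. The mean chi-square per gene between the 2 titled libraries was 3.24, 3.44 and 4.99 on days 3, 7 and 14, against 7.11, 64.3 and 149 between scramble and the library titled KD. This measure grows with depth. On day 14 the Pearson r of log2 CPM was 0.967 between the titled libraries, 0.968 between scramble and titled Rescue and 0.965 between scramble and titled KD, while the median absolute log2 difference of genes of at least 5 CPM was 0.135, 0.406 and 0.381.

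Compared within each day without a test, 76 of the list medians of the titled arms lay outside the central 95% of random lists (77 with a pseudocount of 0.5 CPM). The median of cholesterol synthesis genes was −0.38 in the library titled KD and −0.34 in the one titled Rescue on day 3, 0.47 and 0.45 on day 7, and −1.25 and −1.58 on day 14.

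By day, in the fit added after these results were seen, few genes differed between the siRNA libraries and the scramble library on day 3. Of 16 mast cell, eosinophil and basophil genes 12 fell and 15 were lower when adjusted over the list alone (median −0.80, list test adjusted p = 1.24e-15, adjusted p = 0.0578 with an estimated correlation). EPX fell by 0.95 ± 0.06 (SE, n = 2 siRNA libraries against 1 scramble), CLC, the Charcot-Leyden crystal protein, by 0.81 ± 0.06, RNASE2 by 0.70 ± 0.05, the tryptase TPSAB1 by 0.85 ± 0.07 and the interleukin 5 receptor IL5RA by 1.43 ± 0.18. Cholesterol synthesis genes fell in 12 of 18 cases and in 16 when adjusted over the list alone (median −0.39, adjusted p = 5.62e-18, adjusted p = 0.0578 with an estimated correlation), with HMGCS1 down by 0.63 ± 0.06. Of the transcription factors of the core panel, GATA1 fell by 0.66 ± 0.09, GATA2 by 0.52 ± 0.06 and GFI1B by 0.43 ± 0.06, while TAL1 (adjusted p = 0.125), NFE2 (0.0746), LMO2 (0.833), KLF1 (0.944) and MYB (1.00) did not pass. RHAG and SPTB, proteins of the red cell membrane, fell by 1.39 ± 0.17 and 1.88 ± 0.27, and CSF1, a macrophage growth factor, by 1.14 ± 0.10. CD36, a scavenger receptor, rose by 0.60 ± 0.07.

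On day 3, 23 genes rose and 153 fell of 18943. Megakaryocyte genes fell in 3 of 21 cases (adjusted p = 0.000483, adjusted p = 0.237 with an estimated correlation), with ITGA2B down by 0.51 ± 0.06 and THBS1 by 1.38 ± 0.22. Granulocyte genes fell in 3 of 15 cases and in 6 when adjusted over the list alone (0.000483, and 0.189 with an estimated correlation). Red cell membrane and late erythroid genes each fell in 5 cases, and monocyte genes rose in 3 cases and fell in 1, without a list call. Mitosis genes (median 0.09, adjusted p = 0.000782) and lymphoid genes (median 0.52, 0.0125) lay higher with 0 members past the threshold, and glycolysis and hypoxia (0.00452), stress response (0.0253) and erythroid transcription factor genes (0.0352) lay lower. These 5 had adjusted p = 0.328 to 0.668 with an estimated correlation. The count of 176 genes was 49 without the day 3 library titled KD, 37 without the day 3 one titled Rescue, 93 and 92 without the day 7 ones, and 549 and 543 without the day 14 ones. Without the day 3 library titled Rescue the calls of SPTB (adjusted p = 0.104) and IL5RA (0.0789) were lost, without the one titled KD that of THBS1 (0.0805), and without either that of GFI1B (0.0555 and 0.0754).

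On day 7 the siRNA libraries were lower in stress response genes and in genes of other myeloid lineages. TRIB3, an inhibitor of stress signalling, fell by 3.90 ± 0.07 (adjusted p = 1.96e-15), from 128.5 CPM with scramble to 8.2 and 8.7 CPM in the libraries titled KD and Rescue. Of 18 stress response genes 15 fell (median −1.12, list test adjusted p = 1.82e-09, adjusted p = 0.0605 with an estimated correlation), with DDIT4 down by 1.70 ± 0.06 and PHGDH, of serine synthesis, by 1.67 ± 0.07. Monocyte genes fell in 19 of 20 cases (median −1.62, 1.96e-14, and adjusted p = 0.0605 with an estimated correlation), with CD14 down by 3.11 ± 0.17, and the macrophage genes GPNMB and SPP1 fell by 3.10 ± 0.11 and 2.76 ± 0.11. Granulocyte genes fell in 10 of 15 cases and in 13 when adjusted over the list alone (median −1.07, 1.40e-08), with AZU1 down by 1.56 ± 0.06, ELANE by 1.37 ± 0.06 and MPO by 0.98 ± 0.06. Megakaryocyte genes fell in 19 of 21 cases (median −0.79, 6.17e-10), with ITGA2B down by 0.68 ± 0.06, and mast cell, eosinophil and basophil genes in 15 of 16 (median −0.62, 1.63e-06). Each of these last 3 lists had adjusted p = 0.0605 with an estimated correlation.

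Erythroid genes were lower with the siRNA on day 7 and cholesterol synthesis genes higher. Red cell membrane genes fell in 17 of 22 cases and rose in 1 (median −0.50, list test adjusted p = 1.48e-06, adjusted p = 0.176 with an estimated correlation), with SLC4A1 down by 1.16 ± 0.07 and the blood group protein RHD by 1.16 ± 0.06. Heme synthesis genes fell in 10 of 12 cases (0.000291, and adjusted p = 0.223 with an estimated correlation), with ALAS2 down by 0.53 ± 0.06 and TSPO2 by 2.00 ± 0.12. Late erythroid genes fell in 12 of 25 cases and rose in 2 (0.00374, 0.434 with an estimated correlation). Erythroid transcription factors fell in 10 of 16 cases and rose in 1 (0.00548, 0.537 with an estimated correlation), with SOX6 down by 1.52 ± 0.07 and E2F2 by 1.09 ± 0.06. Globins fell in 4 of 11 cases and rose in 2 (adjusted p = 0.766): HBB fell by 1.17 ± 0.13, HBE1 rose by 2.25 ± 0.16, and HBA2 fell by 0.82 ± 0.17 (adjusted p = 0.0226), a call lost with DESeq2 (0.102), with no filter (0.0989) and without the day 7 library titled KD (0.128) or titled Rescue (0.165). Globins held 1.80% of counts with scramble (Wilson interval 1.79 to 1.80) against 0.906% and 0.944%. Cholesterol synthesis genes rose in 15 of 18 cases (median 0.49, 1.29e-08, and adjusted p = 0.0608 with an estimated correlation), with HMGCS1 up by 1.25 ± 0.06.

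Other lists of day 7 were mixed or moved by less. Glycolysis and hypoxia genes fell in 14 of 21 cases (median −0.60, list test adjusted p = 1.63e-06), with VEGFA down by 1.27 ± 0.06, and DNA replication genes rose in 14 of 22 and fell in 3 (0.00303), both with adjusted p = 0.176 with an estimated correlation. Dendritic genes fell in 5 of 12 cases (0.00698, 0.562 with an estimated correlation), ribosomal protein genes rose in 8 of 32 (0.00196, 0.711 with an estimated correlation) and mitochondrially encoded genes rose in 5 of 13 (0.00901, 0.562 with an estimated correlation). Genes of the TAL1 complex list, which holds TAL1 itself, rose in 2 of 13 cases and fell in 3, with GATA2 down by 0.57 ± 0.06. Mitosis genes rose in 2 of 22 and fell in 5, immediate early genes rose in 5 of 16 and fell in 6, p53 targets rose in 3 of 20 and fell in 6, interferon genes fell in 4 of 23, lymphoid genes fell in 3 of 14, and stem and progenitor genes rose in 2 of 24 and fell in 3, with list adjusted p between 0.0912 and 0.766. IGFBP5, an insulin-like growth factor binding protein, rose by 2.52 ± 0.60 and the neuropeptide GAL by 2.09 ± 0.24. With edgeR 3144 genes rose and 2571 fell of 18943, and without the day 7 library titled Rescue the total was 3800.

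On day 14 cholesterol synthesis genes were lower in the siRNA libraries and stress response genes higher. SCD, which desaturates fatty acids, had a fitted log2 change of −3.29 ± 0.06 (n = 2 siRNA libraries against 1 scramble, adjusted p = 5.39e-15), with 577.4 CPM for scramble and 56.0 and 50.03 CPM in the libraries titled KD and Rescue, and the desaturase FADS1 fell by 2.49 ± 0.07. Cholesterol synthesis genes fell in 15 of 18 cases and rose in 1 (median −1.32, list test adjusted p = 3.09e-08, adjusted p = 0.141 with an estimated correlation), with INSIG1 down by 2.06 ± 0.06, SQLE by 1.87 ± 0.07 and HMGCS1 by 1.48 ± 0.06. APLNR, the apelin receptor, fell by 3.17 ± 0.18 and ACSBG1 by 3.43 ± 0.17. Stress response genes rose in 14 of 18 cases and fell in 1 (median 0.54, 0.000135, and adjusted p = 0.172 with an estimated correlation), with PHGDH up by 1.64 ± 0.09 and the chaperone HSPA5 by 1.04 ± 0.06. With totals as the scaling, 9 stress response genes rose and 2 fell (median 0.17). Immediate early genes rose in 9 of 16 cases and fell in 1 (0.000540, and 0.299 with an estimated correlation), with FOS up by 2.16 ± 0.07 and EGR1 by 2.06 ± 0.09. Monocyte genes rose in 11 of 20 cases (median 0.63, 0.000442, and 0.150 with an estimated correlation), and with totals as the scaling 3 rose and 1 fell. With the day 14 scramble library thinned, 6 monocyte genes rose and 0 fell.

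Proliferation and ribosomal protein genes were lower with siRNA on day 14 and globins higher. DNA replication genes fell in 19 of 22 cases (median −0.47, list test adjusted p = 8.21e-08) and mitosis genes in 21 of 22 (median −0.50, 1.63e-09), both with adjusted p = 0.141 with an estimated correlation. CDT1, which licenses replication, fell by 1.29 ± 0.06, TYMS by 1.23 ± 0.06 and UBE2C, of mitotic exit, by 1.07 ± 0.07. All 32 ribosomal protein genes fell (median −0.79, 1.86e-12, and adjusted p = 0.511 with an estimated correlation), and all 13 mitochondrially encoded genes rose (median 0.91, 8.21e-08, and adjusted p = 0.330 with an estimated correlation), beside the higher mitochondrial share given above. Globins rose in 8 of 11 cases and fell in 2 (median 1.10, adjusted p = 0.0836), with HBB up by 1.35 ± 0.14, and the fetal HBG2 by 1.26 ± 0.08, HBE1 higher by 2.82-fold, while the embryonic HBZ fell by 0.82 ± 0.06. Globins held 6.02% of counts with scramble (Wilson interval 6.01 to 6.02), 11.2% in the library titled KD (11.2 to 11.2) and 11.2% in the one titled Rescue (11.2 to 11.2).

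Several erythroid directions of day 14 depend on the scaling, since totals moved the median of all genes by −0.35 and no filter by −0.20. Late erythroid genes rose in 16 of 25 cases and fell in 5 (median 0.30, list test adjusted p = 0.0116, adjusted p = 0.511 with an estimated correlation) and with totals 9 rose and 11 fell (median −0.06). XPO7 rose by 1.29 ± 0.06 and BPGM, which makes 2,3-bisphosphoglycerate, by 1.15 ± 0.06. Red cell membrane genes rose in 12 of 22 cases and fell in 3, and with totals 5 rose and 12 fell (median 0.18 and −0.19), with EPB41 up by 0.93 ± 0.07 and the water channel AQP1 down by 1.28 ± 0.06. Heme synthesis genes rose in 7 of 12 cases and fell in 4, and with totals 1 rose and 5 fell (median 0.29 and −0.08), with ALAS2 up by 0.90 ± 0.07. Erythroid transcription factors rose in 8 of 16 cases and fell in 5, with totals 4 and 8. Genes of the TAL1 complex list, TAL1 included, rose in 6 of 13 and fell in 3, with totals 3 and 8. LMO2 fell by 0.90 ± 0.07 and GATA2 rose by 0.83 ± 0.08. GATA1 differed by 0.03 ± 0.07 (adjusted p = 0.744) and turned to −0.33 with totals and −0.18 with no filter. KLF1 rose by 0.18 ± 0.06 and TFRC by 0.20 ± 0.06, and both turned negative with totals (−0.18 and −0.17) and with no filter (−0.03 and −0.02), and lost their calls without the day 7 library titled KD (adjusted p = 0.0604 and 0.0507) or titled Rescue (0.0603 and 0.0505).

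The day 14 library titled KD held stem and progenitor transcripts that the other day 14 libraries lacked. CD34 measured 41.1 CPM in it, 0.2 CPM with scramble and 0.1 CPM in the library titled Rescue, and HLF, a stem cell factor, measured 7.32, 0.217 and 0 CPM. 7 genes that were abundant on day 0 and lost by day 3 (WDR49, AREG, ADGRG6, ELN, PRSS2, ACY3 and HLF) exceeded scramble in it by a median of 5.35% of their day 0 level, and by −0.0203% in the library titled Rescue. Stem and progenitor genes rose in 4 of 24 cases on day 14 (median 2.28), and without that library their median was 0.00. Lymphoid genes rose in 3 of 14 cases (median 1.21, and −0.01 without that library) and dendritic genes in 0 of 12 (median 1.29, and −0.08 without it). Interferon genes rose in 5 of 23 cases and fell in 3, and without it 4 rose and 5 fell. Megakaryocyte genes fell in 7 of 21 cases (0.00365, 0.263 with an estimated correlation), granulocyte genes in 3 of 15, mast cell genes fell in 3 of 16 and rose in 2, p53 targets rose in 10 of 20 and fell in 4 (with totals 4 and 5), and glycolysis and hypoxia genes rose in 7 of 21 and fell in 7. Of all genes 3772 rose and 3011 fell of 18943. Scaling by totals kept 70.7% of these 6783 calls in the same direction, and 75 passed in the opposite one. Thinning the day 14 scramble library kept 74.4%. The largest fitted rises, CPNE7 (6.94 ± 1.55) and EVC (6.58 ± 1.59), rest on 0 counts with scramble (floor 0.0725 CPM) against 0.441 and 0.553 CPM (CPNE7) and 0.529 and 0.138 CPM (EVC) in the libraries titled KD and Rescue, and both calls were lost with the scramble library thinned (adjusted p = 0.0645 and 0.0893), as was that of EVC without the library titled KD (0.108).

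**Figure D3:**
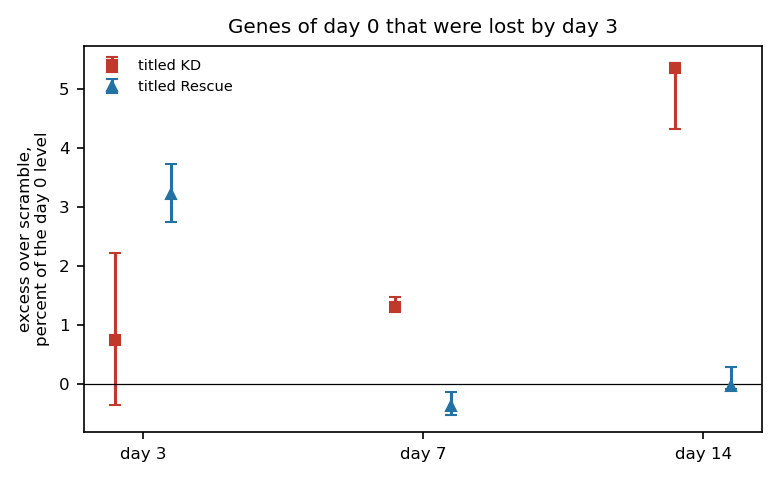
Excess over the scramble library of the same day, as a percent of the day 0 level, for 7 genes abundant on day 0 and lost by day 3, with medians as points and quartiles over the genes as bars. The library titled KD stands at 0.757% on day 3, 1.32% on day 7 and 5.35% on day 14, and the library titled Rescue at 3.22%, −0.358% and −0.0203%.

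**Figure D4:**
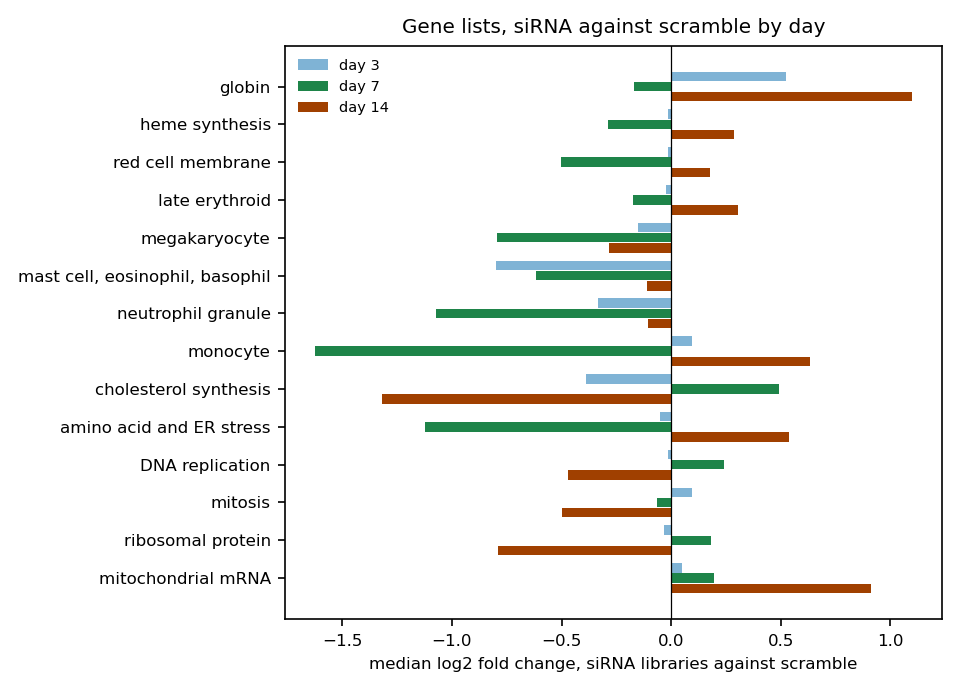
Median log2 change over the tested members of 14 gene lists, siRNA libraries against scramble, with 1 bar per day and list from the fit by day. Cholesterol synthesis goes from 0.49 on day 7 to −1.32 on day 14 and monocyte genes from −1.62 to 0.63, while the day 3 globin bar rests on near-zero counts and the day 14 bars of late erythroid, red cell membrane and heme synthesis genes turn to −0.06, −0.19 and −0.08 with totals as the scaling.

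The difference between the siRNA effects of days 14 and 7 was itself tested. Cholesterol synthesis genes were lower on day 14 relative to day 7 for 17 of 18 members (list test adjusted p = 6.57e-11), with HMGCS1 at −2.72 ± 0.09. Monocyte genes were higher for 20 of 20 (6.57e-11), stress response genes for 16 of 18 (3.24e-09) with TRIB3 at 4.43 ± 0.10, and DNA replication genes were lower for 19 of 22 (2.91e-08). These 4 lists had adjusted p = 0.0792 with an estimated correlation. Red cell membrane genes were higher for 17 of 22 and lower for 1 (3.39e-05, 0.219 with an estimated correlation), and globins were higher for 9 of 11 and lower for 2 (0.211), with HBB at 2.52 ± 0.19 and HBZ at −1.88 ± 0.09. With edgeR the effect was higher on day 14 for 3645 genes and lower for 3515. Of 2896 genes called on both days, 1903 (65.7%) had opposite directions, 943 of them lower on day 7 and higher on day 14 and 960 the reverse. Independent calls would share 2046 genes, 512 of them lower on day 7 and higher on day 14 and 500 the reverse. Across all tested genes, which are not independent, the effects of the 2 days correlated weakly (r = −0.132), so this is no general reversal.

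Genes that set the K562 clones apart were followed in the CD34+ cells. Since edgeR called 0 genes in K562 (1539 with an unadjusted p under 0.05, and 185 called by DESeq2), the 200 genes of smallest p in each direction were used. Of those lower in the K562 clones 160 were tested in CD34+ cells, where they lay lower with siRNA on day 7 (median −0.32, adjusted p = 0.000716) and higher on day 14 (median 0.37, adjusted p = 0.00416), with adjusted p = 0.0532 with an estimated correlation for both. On day 3 (median −0.0014, adjusted p = 0.571) and across days (median 0.0013, adjusted p = 0.852) they did not pass. Of those higher in K562, 158 were tested and had medians of −0.17 on day 7 (adjusted p = 0.0794) and 0.11 on day 14 (0.719).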

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

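Of the tests in this part, the interaction tests, the shift along the change from day 7 to day 14, the lone scramble library, the tests of day 0 RNA, of siRNA-kept progenitors and of the titled KD arm alone, and the exchange of titles were chosen only after the result was seen. The tests of the whole course of maturation and of day 3 progenitors, and the bounds for scaling by totals, thinning and the left-out library, were set before their results, although those 3 settings were added after seeing the data.

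The siRNA effect differed between days for many genes, by the test of the difference itself. It differed for 3266 genes between days 7 and 3, for 7160 between days 14 and 7 and for 4863 between days 14 and 3. Without either day 3 siRNA library the first count was 1680 and 1683, without either day 7 one 1881 and 1804, and without either day 14 one 5323 and 5311. Genes of the core panel were taken here where both days passed in opposite directions. For these the log2 difference of day 14 minus day 7 was 0.81 for TAL1, 1.40 for GATA2, 0.87 for NFE2 and −0.57 for GFI1B. It was 2.52 for HBB, 1.97 for HBA1, 2.16 for HBA2, 1.43 for ALAS2 and 1.73 for SLC4A1. Outside this choice the difference was −0.93 for LMO2 (adjusted p = 3.52e-06), −0.75 for HBE1 (0.00433), −0.11 for GATA1 (0.389), 0.07 for KLF1 (0.590) and −0.36 for MYB (0.639). For HBA1 the call was lost with DESeq2 (2.02, adjusted p = 0.402). For TFRC the difference was 0.37, and its call was lost with totals as the scaling (0.06, adjusted p = 0.612) and with no filter (0.15, adjusted p = 0.225).

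Opposite siRNA effects on days 7 and 14 were weighed against technical and culture explanations. Scaling (7930 genes differed with totals, among them 5844 of the 7160), the deep day 14 scramble library (5956 after thinning, 5717 of the 7160) and day 0 RNA in the day 14 library titled KD (7264 without it, 6266 of the 7160) are each argued against as the whole cause, since each count stayed above the bound set beforehand. Cultures that lag and then overtake along changes shared by the whole course are argued against too. Across genes, which are not independent, the day 14 effect correlated with the day 7 minus day 3 change at r = −0.175. The day 7 effect correlated with the day 14 minus day 3 change at −0.0194. Over 11063 genes the day 7 minus day 3 and day 14 minus day 7 changes correlated at 0.406. A culture ahead on day 14 need not repeat the early change, so stages set apart by later changes are not excluded. Cultures apart along the step from day 7 to day 14 cannot be told apart from other siRNA effects, because that change holds the same libraries: over 11063 genes the day 14 effect correlated with it at r = 0.241 and the day 7 effect at −0.171, while effects shuffled across genes gave 0.211 to 0.264 and −0.227 to −0.176 when placed on the siRNA libraries but −0.233 to −0.176 and 0.150 to 0.207 when placed on scramble, and over all 18943 genes 0.221 and −0.0807 against 0.247 to 0.285 and −0.237 to −0.199 on siRNA and −0.252 to −0.206 and 0.176 to 0.217 on scramble. Since each day has 1 scramble library, a scramble culture that stood apart for another reason cannot be told apart from an effect of the siRNA, whose own biology stays open.

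Stem and progenitor transcripts in the day 14 library titled KD (CD34 41.1 CPM against 0.2 with scramble) may come from RNA or reads of the day 0 sample. Genes lost by day 3 and genes still present on day 3 were in excess by 5.35% and 5.22% of their day 0 level, a ratio of 1.02, and all 77 of the latter exceeded scramble. Progenitors like those of day 3 are argued against, because 18 genes abundant on day 3 and low on day 0 had a median share of 0.433%. The share of −0.0203% in the day 14 library titled Rescue argues only against progenitors kept by the siRNA in both titled arms. By its title that library also received Tal1, which the siRNA effect may not outlast. Progenitors kept by the siRNA without Tal1 therefore cannot be excluded. Day 0 cells kept by the treatment of the titled KD arm alone cannot be told apart from this, since the share was 1.32% in the day 7 library titled KD but also 3.22% in the day 3 library titled Rescue. Whether such material entered as cells, RNA or reads is open, and without this library 6529 genes passed on day 14 against 6783 with it.

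TAL1 was alike in the titled KD and titled Rescue libraries, with a log2 difference of 0.083 (titled Rescue minus titled KD). The labels disagree on which arm received Tal1, and by TAL1 an exchange of titles cannot be told apart from the titles as given. The difference is smaller than its standard error of 0.21 in the additive fit. That error also holds the change of the siRNA effect between days, which both titled arms share, so it cannot decide the question. On days 3, 7 and 14 TAL1 measured 51.9, 340 and 1916 CPM in the libraries titled KD. In those titled Rescue it measured 54.6, 351 and 1902 CPM, on the scaling that includes day 0. Relative to scramble the libraries titled KD and Rescue stood at 0.814 and 0.856 on day 3 and at 0.819 and 0.845 on day 7. On day 14 they stood at 1.35 and 1.34. Counting intervals of the titled arms overlapped on each day, so no added TAL1 RNA was visible in only 1 of them. The count columns of the arm titled Rescue are named OE and those of the arm titled KD are named KD, which goes with the titles if OE stands for overexpression of Tal1, but a name is not a measured value. A Tal1 construct that lacks the counted parts of the gene was not analysed here.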

How the results depend on the processing

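The fit by day and all its alternatives, scaling by totals, thinning of the day 14 scramble library and omission of the day 14 library titled KD were chosen after seeing the data. No paired analysis was possible because no replicate numbers link the samples, and the only blocks are day and arm in the additive fit. Of the single-gene values, 1838 were held unchanged. Their call and its direction stayed, or neither setting passed, in which case direction was not compared. A further 46 lost and 36 gained a call, and 6 with a call in either setting reversed. K562 values with a clone left out were judged by the spread between the clones, and 4 moved beyond it. Counts were held unchanged within 1.5 times, and correlations within the standard deviation of simulated data. By these bounds 151 were unchanged and 39 moved. In K562, 1 gene passed with totals, 745 with no filter, 185 with DESeq2 and 1566 with the CD34+ dispersion in a likelihood ratio test, against 0. Leaving out a clone leaves no residual degrees of freedom and gives values with no test. With no filter 30 genes passed for siRNA against scramble, 6 for the titled KD arm, 4 for the titled Rescue arm and 355 for the siRNA on day 3. With DESeq2 the siRNA had 24, the titled KD arm 33, the titled Rescue arm 40 and titled Rescue against titled KD 50. With a mean of at least 5 CPM, which tests fewer genes, 5654 passed for day 7 against day 3 and 8851 for day 14 against day 3. Leaving out 1 day, arm or library gave 0 to 1 for the siRNA across days, 3922 to 10792 for day 7 against day 3, 6849 to 11892 for day 14 against day 7, 37 to 549 for the siRNA on day 3, 3800 to 7576 on day 7, and 1680 to 5323 for day 7 minus day 3. On day 14 GATA1 reversed to −0.33 with totals and −0.18 with no filter, KLF1 to −0.18 and −0.033, and TFRC to −0.17 and −0.018. List calls went from 93 to 0 with an estimated correlation, 52 with fry and 75 with mixed fry in the planned comparisons, and from 74 to 0, 81 and 122 in the fit by day. The K562 sets held 0 tested genes as planned and 318 as the 200 of smallest p in each direction. The correlation of both arms was 0.571 with totals, 0.502 with no filter and 0.587 at 5 CPM. Apart from fewer genes or libraries, the cause was not tested. The targeted RNA had 4 to 99 counts per library.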

Other observations

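The tests of other splits of the libraries were set before their result, and SCD was followed across days only after its values were seen.

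A fatty acid gene outside the lists followed cholesterol synthesis through the cultures. SCD measured 148.1 CPM on day 0, and 419.7 CPM with scramble siRNA on day 3 against 326.2 and 323 CPM in the libraries titled KD and Rescue. On day 7 it measured 655.2 CPM with scramble and 1024 and 1011 CPM with siRNA, and on day 14 577.4, 55.96 and 50.03 CPM. This was the direction of the cholesterol list on each day.

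The number of genes called was compared with that of other splits of the same libraries. For siRNA against scramble across days, 10 of 81 splits gave at least the 1 gene of the real split fitted as 2 groups, so chance cannot be excluded, and the highest other split gave 2560 genes. That split set the day 14 libraries titled KD and Rescue with the day 7 scramble library against the rest, which points to a structure of the samples. Within days it contrasts siRNA and scramble in opposite directions on days 7 and 14, the difference tested above with 7160 genes. For titled KD against scramble the real value was 0 and the highest other split gave 15, for titled Rescue against scramble 0 and 1, and for titled Rescue against titled KD 0 and 707, each with 10 of 10 splits at least as high. With a real value of 0 every split is at least as high, so these shares say nothing about chance. For the days the real splits gave 10399 (day 7 against 3), 9194 (day 14 against 7) and 12796 (day 14 against 3), the highest other split gave 0, and 1 of 10 splits, the real one, was as high. 10 splits are too few for a share under 0.05.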
